A study of Mus musculus with 6 samples.

How the data were processed

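RNA of peritoneal macrophages from old (18 months) and young (2 months) mice had been sequenced after preparation with the TruSeq protocol, per the labels, with 3 libraries of each age. The deposited table holds 1 value per Ensembl gene and library for 19973 genes. Its values are of the kind signal, that is counts normalized by the authors: reads per gene divided by a size factor per library. The submitters' processing notes name DESeq2 and the mouse build mm10 and give no versions. The aligner, the read counter, the annotation release and whether counting used strand are not given in the sources used here. The lowest total of a listed gene was 2 reads over the 6 libraries.

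Each column consists of whole multiples of a single step, so whole reads could be recovered by division. The share of values that came out whole was 100% in every library, within a tolerance of 0.01 reads. Median-of-ratios size factors recomputed from these reads equalled the reciprocals of the steps, from 0.787 in old replicate 3 to 1.18 in young replicate 3. Read totals lay between 8163000 and 13008000. The most abundant gene, mitochondrial ribosomal RNA mt-Rnr2, took 7.13% to 9.44% of reads. Of the identifiers, 19917 matched a symbol and 56 did not. Gene positions, biotypes and overlaps come from GENCODE release M21 on GRCm 38, the assembly that mm10 names. Positions count from 1 and span the whole gene.

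Before averaging, the 15 pairs of libraries were compared by a chi-square statistic per gene over genes with at least 50 reads in the pair. Its median was 1.49 times the value expected from sampling noise for old replicates 1 and 2 and 1.76 times for young replicates 1 and 2, the nearest pairs within each age. Between ages it was 8.21 to 19.2 times. No pair agreed within sampling noise, and each library counts as 1 sample.

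The comparison used limma 3.58.1 in R 4.3.3 with a trend in the prior variance on log2(normalized count + 1). Genes needed a mean of at least 10 over the 6 libraries, which left 11795 and set aside 8178. Fold changes on this scale are old minus young and understate the change of low genes. Fold values in the text are ratios of mean normalized counts. P-values were adjusted with Benjamini-Hochberg over all tested genes at a threshold of 0.05. Adjusted p-values of single genes are from limma unless another tool is named. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, adjusted over the tested lists, with camera at an estimated correlation and fry beside it. All list tests are 2-sided.

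The design, the alternatives and the 30 gene lists were fixed before the data were examined. So was the rule for named genes. It takes Gpr18 whatever its value. It takes the 12 genes with the highest and the 12 with the lowest fold change among those that passed, had a mean of at least 50, showed no overlap between old and young libraries (which chance alone gives 10% of genes with 3 against 3) and were not predicted gene models or pseudogenes. It takes up to 4 passing members of each list with the smallest adjusted p, and 2 members with the highest mean where none passed. Some results are left out of the text because they are withheld for evaluation. Genes named outside this rule are marked as chosen after their values were seen.

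The test was run first on simulated counts drawn from the means, library sizes and dispersions of the real libraries, with 200 changed genes in each of 5 runs over about 11684 tested genes. For this comparison it recovered 55.6% of genes changed 1.5-fold, 83.4% at 2-fold, 94.0% at 4-fold and 98.8% at 8-fold. False calls made up 7.19% of all calls. The simulated genes were drawn independently, without differences between libraries that many genes share. These rates may therefore not carry over to the real libraries.

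Alternatives fixed beforehand were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile normalization, median centring, limma without the trend, array quality weights, robust empirical Bayes, the replicate number as a block, each library left out, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, and a fold change limit. Alternatives added after seeing the data were removal of per-library trends with transcript length and GC content (natural splines with 4 degrees of freedom), the summed counts of 1162 TEC gene models as a covariate, protein-coding genes only, and leaving out both libraries numbered 3.

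Without knowledge of strand, reads of overlapping genes on opposite strands cannot be told apart. This concerns Gpr18 and 36 of the 123 other genes under the naming rule, whose values are uncertain to that extent. Examples are Gpr18 with Ubac2, Mki67 with Gm45240, Cenpf with Gm37239, Plk1 with Gm44985, Ch25h with Gm26902, Ube2c with Tnnc2, Ccna2 with Exosc9, Irf7 with Phrf1, Mmp12 with Mmp1b, Fn1 with Apol7d, Ciita with Dexi, Stab1 with Nt5dc2 and Cx3cr1 with several neighbours. Values of near-identical copies, such as immunoglobulin segments, Hspa1b and its neighbour Hspa1a, and C4b, are uncertain where the counting could split their reads. Counting intervals and floors cover counting error only.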

Results

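The data set holds messenger RNA profiles of peritoneal macrophages from male C57BL/6 mice, a widely used inbred laboratory strain, that were either 18 months (old) or 2 months (young) of age. Zymosan A, a yeast cell wall particle that starts a self-limiting inflammation, had been injected into the peritoneal cavity at 200 µg per mouse. Cells were collected by lavage after 72 hours and cultured overnight, unattached cells were washed off, and the attached cells were kept for 6 hours with vehicle (phosphate-buffered saline). There were 3 old and 3 young libraries, and only vehicle libraries were analysed here. The series title is about the pro-resolving lipid resolvin D2 and its receptor Gpr18 in ageing, and the comparison below gives the age difference without the lipid. Recovered read totals, rounded, were 9198800, 13008000 and 8163000 in old replicates 1, 2 and 3 and 9795600, 11520000 and 12482000 in young replicates 1, 2 and 3, so depth did not separate the ages. The labels speak of 3 mice per group and of triplicate sequencing of each mouse's RNA, without saying which of these a library is, so p-values measure the spread between these libraries, which may be partly technical.

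Old macrophage cultures carried far fewer mitotic transcripts than young ones and more transcripts of the matrix proteases Mmp8 and Mmp12 and of genes for lipid uptake, the lysosome and antioxidant enzymes. As lists, none of these passed in camera with an estimated correlation. The adjusted p was 0.339 for the cell cycle, 0.393 for lipid uptake and 0.532 for the lysosome and the antioxidant lists. B cell and mast cell genes were also higher in old, with list medians of 4.35 and 3.18, and Mmp8 belongs to the neutrophil list as well. Of 11795 genes tested, 4183 differed (35.5%), with 2107 higher and 2076 lower in old (limma, Benjamini-Hochberg adjusted p under 0.05). A change of at least 1 on the log2 scale was reached by 1040 of them, 463 higher and 577 lower. The first principal component held 71.5% of the variance and separated the ages. The second held 18.2% and set old replicate 3 and young replicate 3 at opposite ends. Old replicate 3 also had 1.35% of reads on ribosomal RNA genes other than the mitochondrial ones, against 0.0177% to 0.154% in the other libraries. Without the libraries numbered 3 (chosen after seeing the data) 6964 genes passed. Among 30 gene lists, 27 had at least 5 tested members and 16 of these differed (camera, adjusted p under 0.05), 13 toward higher and 3 toward lower values in old. With an estimated inter-gene correlation no list passed (0 of 27), 3 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.249. The rotation test fry, which asks whether a list's genes move one way, called 17. Other splits of the libraries into groups of 3, which mix the ages, gave 6 to 13 lists with camera at the preset correlation. Every group in these splits holds unequal numbers of old and young libraries, so part of the age difference remains in them. They therefore cannot show how often lists are called without an age difference. Since no list passed with an estimated correlation, a list call alone is weak evidence for an age difference.

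**Figure D1:**
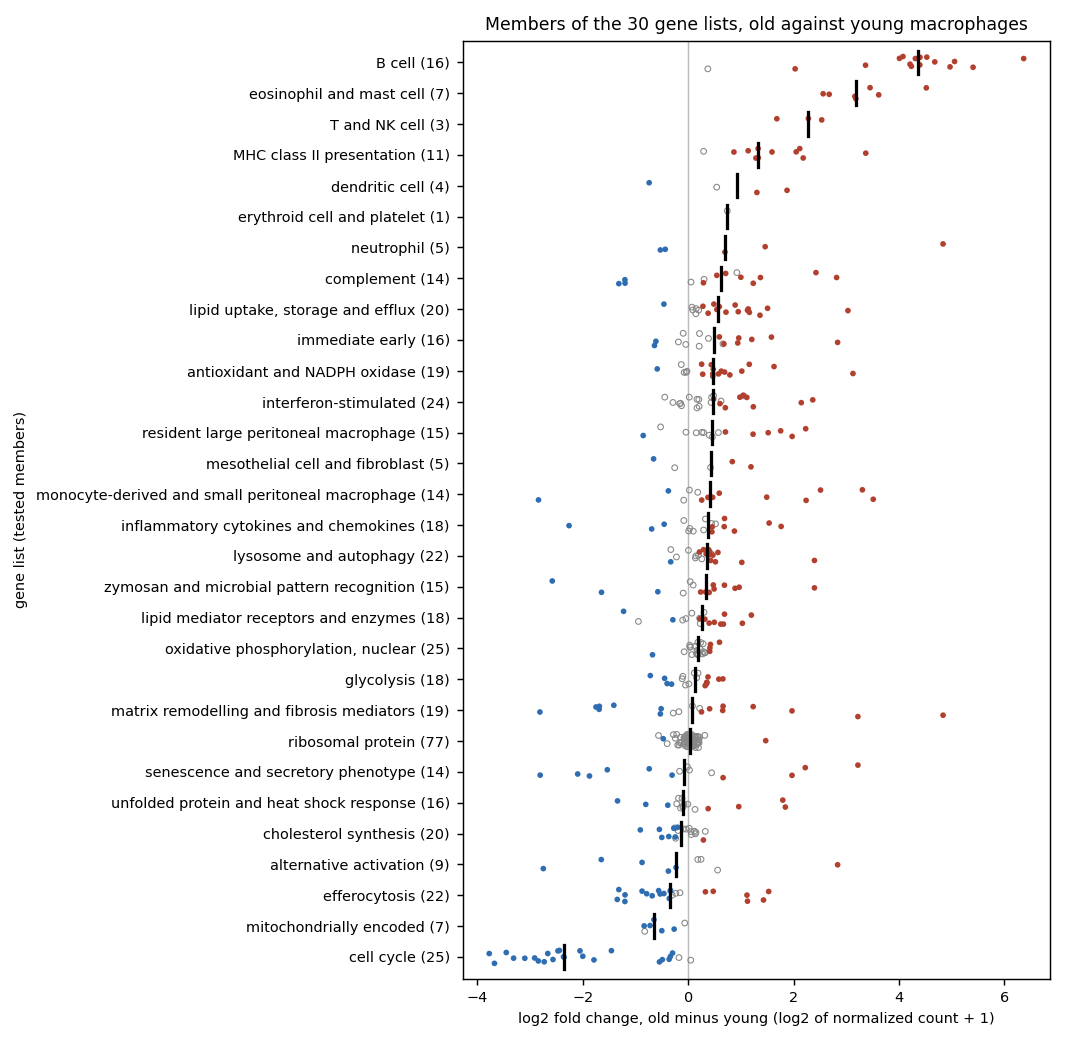
Log2 fold change (horizontal axis, old minus young, on the log2 scale of normalized count + 1) of each tested member of the 30 gene lists (vertical axis, number of tested members in brackets). Filled points passed the test (red higher and blue lower in old), open points did not, and black bars are list medians, from -2.37 for the cell cycle to 4.35 for B cell genes.

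The 12 genes with the highest fold changes under the naming rule included 6 B cell genes. They were the immunoglobulin segments and constant regions Igkv14-126, Igkc, Ighv11-2 and Ighm, the surface protein gene Ms4a1 (CD20) and the antigen receptor component Cd79b. A pair of mast cell proteases, Cma1 and Cpa3, were also among them. The remaining 4 were the collagenase gene Mmp8, with a log2 fold change of 4.84 ± 0.12 (SE; limma adjusted p = 3.67e-08), the macrophage elastase Mmp12 at 3.22 ± 0.11, the thyroid hormone deiodinase Dio2 at 3.72 and the interleukin-36 gamma gene Il1f9 at 3.35. Mmp8 (chromosome 9, 7558456 to 7568485) had 8169 ± 976 normalized counts in old and 285 ± 37.6 in young libraries (SD, n = 3 each), a 28.7-fold difference of means. Mmp12 (chromosome 9, 7344381 to 7369499) had 25838 ± 3450 and 2759 ± 252 normalized counts, 9.36-fold.

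Of the 12 genes with the lowest fold changes, 5 act in DNA replication or mitosis, namely Pif1, Plk1, Cenpf, Ube2c and Aspm. Pmepa1, an inhibitor of SMAD signalling induced by TGF-beta, was lowest of all with a log2 fold change of -5.31 and 6.21 ± 4.35 against 234 ± 20.6 normalized counts (SD, n = 3 each). Phgdh, the first enzyme of serine synthesis (chromosome 3, 98313170 to 98339990), had 29.2 ± 6.11 against 430 ± 59.5 normalized counts and was 14.7-fold higher in young. Ch25h, the cholesterol 25-hydroxylase (chromosome 19, 34473778 to 34475164), had 84.3 ± 10.7 against 1144 ± 46.1 and was 13.6-fold higher in young (limma adjusted p = 4.46e-08). The others were the scavenger receptor relative Fcrls at -4.21, Tmeff1 at -4.12, the aquaglyceroporin Aqp9 at -3.76 and the sulfotransferase Chst1 at -3.60.

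Proliferation genes fell together. In the cell cycle list 23 of 25 members were lower in old, 0 were higher, and 23 passed adjusted over the list alone. The list median was -2.37 (camera adjusted p = 3.36e-19; adjusted p = 0.339 with an estimated correlation). Mki67, the gene of the proliferation antigen Ki-67 (chromosome 7, 135689784 to 135716361), had 1353 ± 90.0 normalized counts in old and 11601 ± 550.5 in young libraries (SD, n = 3 each), 8.58-fold higher in young. Cenpf, a kinetochore protein gene, was 12.9-fold, the mitotic motor gene Kif11 6.36-fold and the cyclin gene Ccna2 5.93-fold higher in young. The subunits of the replicative helicase moved less. Singled out after their values were seen, Mcm2, Mcm3, Mcm4, Mcm5 and Mcm7 lay between -0.30 and -0.54, whereas Mcm6 at -0.17 and the replication clamp gene Pcna at 0.05 did not pass.

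Genes of lipid handling rose. In the list of lipid uptake, storage and efflux 14 of 20 members were higher in old, 1 was lower and 16 passed adjusted over the list alone, with a median of 0.57 (camera adjusted p = 4.92e-07; adjusted p = 0.393 with an estimated correlation). Lpl, the lipoprotein lipase gene (chromosome 8, 68880491 to 68907448), had 21024 ± 446 against 2574 ± 202 normalized counts (SD, n = 3 each), 8.17-fold higher in old. Pparg, a lipid-sensing nuclear receptor gene, was 2.87-fold, the sterol exporter gene Abcg1 2.58-fold and the fatty acid carrier gene Fabp5 2.21-fold higher in old. The lower member, named after its value was seen, was the other sterol exporter gene, Abca1, at -0.46. Cholesterol synthesis as a list did not pass (median -0.14, camera adjusted p = 0.165), with 1 member higher and 7 lower of 20, and 10 passing adjusted over the list alone. With 0 members higher, 5 were lower without old replicate 1, 4 without old replicate 2 or young replicate 1, and 2 without young replicate 2. With 1 library left out, the list median ran from -0.20 (without old replicate 2) to -0.06 (without young replicate 3). The clearest member of the cholesterol list was Stard4, a sterol carrier gene, at -0.91, followed by Dhcr7 at -0.50.

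Lysosomal and antioxidant genes rose as well. The lysosome and autophagy list had 12 members higher and 1 lower of 22, 18 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.00115; adjusted p = 0.532 with an estimated correlation). Under quantile normalization this list lost its call (0.0569, the highest of 20 alternatives, from 1.42e-05). Without old replicate 1, young replicate 1 or young replicate 2 it had 7 members higher and 0 lower. Cathepsin K (Ctsk) had 1348 ± 160 against 254 ± 19.3 normalized counts (SD, n = 3 each), 5.30-fold higher in old, and cathepsin L (Ctsl) was 2.03-fold higher. In the antioxidant and NADPH oxidase list 14 of 19 members were higher and 1 was lower, 15 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 6.35e-05; adjusted p = 0.532 with an estimated correlation). Nqo1, a quinone reductase gene (chromosome 8, 107388225 to 107403206), had 1297 ± 137 against 147 ± 15.3 normalized counts, 8.79-fold higher in old. Prdx1, a peroxiredoxin gene, was 3.09-fold and catalase (Cat) 2.24-fold higher, while the lower member, chosen after its value was seen, was heme oxygenase Hmox1 at -0.59.

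**Figure D2:**
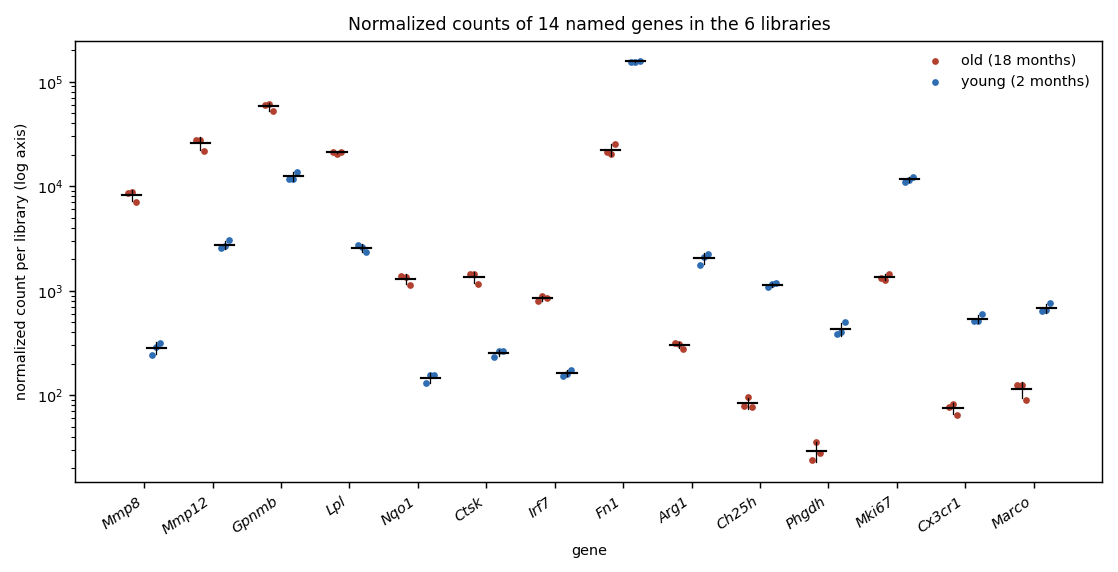
Normalized counts (vertical axis, log scale) of 14 named genes (horizontal axis) in the 3 old (red) and 3 young (blue) libraries, with black bars for means and thin lines for 1 SD either side. Old and young libraries do not overlap for any of the 14 genes, with Lpl at 21024 against 2574 and Mki67 at 1353 against 11601.

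Matrix genes moved both ways. The list of matrix remodelling and fibrosis mediators had 8 members higher and 7 lower of 19, 16 adjusted over the list alone, and no direction as a list (median 0.08, camera adjusted p = 0.617). Besides Mmp8 and Mmp12, Fn1, the fibronectin gene (chromosome 1, 71585520 to 71653200), had 22353 ± 2776 normalized counts in old and 156400 ± 1929 in young libraries (SD, n = 3 each), a log2 fold change of -2.81 (limma adjusted p = 4.12e-07). The growth factor gene Pdgfa was 3.23-fold higher in young. The senescence and secretory list was also divided, with 4 members higher and 6 lower of 14, 10 adjusted over the list alone (median -0.09, camera adjusted p = 0.617). Mmp12 and Gpnmb, a lysosomal glycoprotein gene with 57916 ± 5128 against 12416 ± 1228 normalized counts, were higher in old. The nuclear lamina gene Lmnb1 was 3.67-fold and Igfbp4, which binds insulin-like growth factors, 4.27-fold higher in young. The cyclin-dependent kinase inhibitor genes Cdkn1a (-0.74) and Cdkn2b (-1.53), singled out after their values were seen, were lower in old.

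Genes for the uptake of dying cells mostly fell. Of 22 tested members of the efferocytosis list, 13 were lower and 6 higher in old, 21 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.0212; adjusted p = 0.532 with an estimated correlation). Stab1, a scavenger receptor gene, had 7629 ± 608 against 19358 ± 723 normalized counts (SD, n = 3 each), 2.54-fold higher in young, and the complement component C1qc was 2.29-fold higher in young. Anxa1, the annexin A1 gene, was 2.90-fold and the bridging protein gene Mfge8 2.71-fold higher in old. The complement list, which shares 3 C1q genes with it, had 8 members higher and 3 lower of 14, 12 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.0212; adjusted p = 0.601 with an estimated correlation). Its 3 lower members were C1qc and, named after their values were seen, C1qa and C1qb, whereas C3 was 2.58-fold, C4b 2.35-fold and the anaphylatoxin receptor gene C3ar1 2.00-fold higher in old. The complement call was lost with a mean of at least 50 as filter (camera adjusted p = 0.213), under quantile normalization (0.0831) and with length and GC trends removed (0.0650), and over 20 alternatives its adjusted p ranged from 0.00434 to 0.213.

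Alternative activation genes did not pass as a list (median -0.23, camera adjusted p = 0.272), with 1 member higher and 5 lower of 9, 6 adjusted over the list alone. Arg1, the arginase 1 gene (chromosome 10, 24915221 to 24927484), had 301 ± 19.3 against 2040 ± 242 normalized counts (SD, n = 3 each), 6.77-fold higher in young. The haemoglobin scavenger receptor gene Cd163 was 3.30-fold higher in young. The rising member was the transcription factor gene Egr2, 7.21-fold higher in old, which also belongs to the immediate early list. That list, fixed as a sign of handling stress, had 7 members higher and 2 lower of 16, 10 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.00462; adjusted p = 0.532 with an estimated correlation), and the phosphatase gene Dusp1 was 3.04-fold higher in old.

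Receptors for microbial patterns moved apart. In the list of zymosan and microbial pattern recognition 9 of 15 members were higher and 3 lower, 12 adjusted over the list alone, without a call for the list (median 0.33, camera adjusted p = 0.0948). Clec4n, which encodes the fungal receptor dectin-2, had 3594 ± 388 against 684 ± 99.4 normalized counts (SD, n = 3 each), 5.25-fold higher in old. Tlr2, a receptor for zymosan (chromosome 3, 83836272 to 83841767), had 1059 ± 75.6 against 3321 ± 385, 3.14-fold higher in young, and the scavenger receptor gene Marco was 5.97-fold higher in young. The list passed under 4 of 20 alternatives, among them without young replicate 3 (camera adjusted p = 0.0405, range 0.0138 to 0.452). Inflammatory cytokines and chemokines had 7 members higher and 3 lower of 18, 10 adjusted over the list alone, and did not pass as a list (median 0.39, camera adjusted p = 0.0749). It passed under 5 of 20 alternatives, among them without old replicate 3 (0.0285, range 0.0174 to 0.275). With 1 library left out, its median ran from 0.24 (without old replicate 1) to 0.46 (without old replicate 2). The neutrophil chemoattractant gene Cxcl3 was 3.41-fold higher in old, and the monocyte chemoattractant gene Ccl12 was 4.94-fold and the inflammasome sensor gene Nlrp3 1.61-fold higher in young.

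Interferon-stimulated genes rose in part. Of 24 tested members 9 were higher and 0 lower in old, 10 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.00115; adjusted p = 0.407 with an estimated correlation). Irf7, a regulator of interferon genes, had 845 ± 42.4 against 163 ± 11.2 normalized counts (SD, n = 3 each), 5.17-fold higher in old, and the antiviral synthetase gene Oas3 was 4.44-fold higher. The other 15 members did not pass, among them, looked up afterwards, Isg15 at -0.14 and Ifit1 at 0.21.

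Lipid mediator genes, the list closest to the series title, had 9 members higher and 2 lower of 18, 12 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0212; adjusted p = 0.532 with an estimated correlation). Alox5, the 5-lipoxygenase gene (chromosome 6, 116410077 to 116461178), had 835 ± 42.6 against 363 ± 21.05 normalized counts (SD, n = 3 each), 2.30-fold higher in old. Fpr2, a receptor gene for lipoxin A4 and annexin A1, was 2.03-fold and the phospholipase gene Pla2g4a 1.54-fold higher in old. Ptgs1, the cyclooxygenase-1 gene, was 2.35-fold higher in young. Gpr18 (chromosome 14, 121911253 to 121915781, minus strand, sharing its position with Ubac2 on the other strand) was close to the limit of detection and below the filter of the test. It had 5 to 13 reads per old and 2 to 5 per young library, or 7.81 ± 2.86 and 2.70 ± 1.47 normalized counts (SD, n = 3 each). Each of the 3 old libraries lay above each of the 3 young ones, with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. B cell and T and NK cell genes were higher in the same old libraries. Which cells the Gpr18 reads came from was not tested. Without the filter the log2 fold change of Gpr18 was 1.28 ± 0.51 (SE; limma adjusted p = 0.104). It passed in a fit without the filter to protein-coding genes only, an alternative added after seeing the data (limma adjusted p = 0.0341, range over alternatives 0.0341 to 0.261).

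As lists, markers that separate peritoneal macrophage subsets did not split along the subsets. In the resident large peritoneal macrophage list 6 of 15 members were higher and 1 was lower, 11 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.00689; adjusted p = 0.532 with an estimated correlation). The coagulation factor gene F10 was 4.71-fold and Serpinb2 2.33-fold higher in old, and without old replicate 3 the counts were 11 higher and 1 lower. Looked up afterwards, Gata6 at -0.52 did not pass and Timd4 lay below the filter. In the monocyte-derived and small macrophage list 9 of 14 members were higher and 2 lower, 11 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.00689; adjusted p = 0.596 with an estimated correlation). Clec4a1, a C-type lectin gene, was 4.73-fold, the integrin gene Itgax 2.81-fold and the transcription factor gene Irf4 6.09-fold higher in old. Ly6c2, looked up afterwards, was 10.7-fold higher in old. Irf4 was at 76.2 normalized counts in old replicate 3 and at 127 and 129 in old replicates 1 and 2. Whether its reads came from other cells was not tested. Cx3cr1, the fractalkine receptor gene, had 74.8 ± 8.99 against 541 ± 48.9 normalized counts (SD, n = 3 each), 7.23-fold higher in young.

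Genes of other cell types were higher in the old libraries. In the B cell list 15 of 16 tested members were higher and 0 lower, 15 adjusted over the list alone, with a median of 4.35 (camera adjusted p = 3.06e-10; adjusted p = 0.339 with an estimated correlation). Ighm, the immunoglobulin mu constant region (chromosome 12, 113418558 to 113422730), had 1408 ± 501 against 39.5 ± 5.87 normalized counts (SD, n = 3 each), 35.6-fold higher in old. For Igkv14-126 the young libraries held 2 reads in all against 779, a ratio of 462 with a 95% counting interval of 128 to 3825. Cr2, chosen after its values were seen, had no read in young (0 against 70) and was at least 27.4-fold higher in old, taking 3 reads over the young group as the floor, and the list median with Cr2 at this bound was 4.35. In the eosinophil and mast cell list 7 of 7 members were higher, 7 adjusted over the list alone, with a median of 3.18 (camera adjusted p = 6.22e-06; adjusted p = 0.249 with an estimated correlation), and the chymase gene Cma1 was 11.6-fold higher at 131 ± 2.19 against 11.3 ± 3.40. The T and NK cell list had 3 tested members, fewer than the list test required, and 3 were higher, 3 adjusted over the list alone, among them Il7r, 3.21-fold, which other leukocytes can also express. Without the filter 16 of 19 members of this list were higher and 0 lower, with a median of 2.40 (camera adjusted p = 2.16e-10; adjusted p = 0.152 with an estimated correlation).

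The remaining cell type lists had no camera call. Neutrophil genes had 3 members higher and 2 lower of 5, 5 adjusted over the list alone (median 0.70, camera adjusted p = 0.181), with Mmp8 and S100a8 (2.76-fold) higher and Padi4 at -0.43, and fry called the list higher in old (adjusted p = 2.21e-04). Mesothelial and fibroblast genes had 2 higher and 1 lower of 5, 4 adjusted over the list alone (median 0.42, camera adjusted p = 0.531), with the collagen gene Col3a1 at 0.84 and Col1a1 at -0.66. Dendritic cell genes had 4 tested members, 2 higher and 1 lower, 3 adjusted over the list alone, with Ccr7 4.09-fold higher in old and Cd24a at -0.74, and without the filter 12 members did not pass as a list (camera adjusted p = 0.108). Of the erythroid and platelet list 1 gene was tested, Ppbp, at 0.74 (limma adjusted p = 0.0896), which passed adjusted over the list alone (1 of 1).

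MHC class II genes, which macrophages and B cells both express, were higher in old in 10 of 11 members and lower in 0, 11 adjusted over the list alone, with a median of 1.33 (camera adjusted p = 3.56e-06; adjusted p = 0.508 with an estimated correlation). Cd74, the invariant chain gene (chromosome 18, 60803848 to 60812652), had 5645 ± 1028 against 2222 ± 169 normalized counts (SD, n = 3 each), 2.54-fold higher in old. The transactivator gene Ciita was 4.36-fold and H2-Ob, known mainly from B cells, 12.5-fold higher. Old replicate 3 had lower levels of both groups of genes than the other old libraries. The median log2 ratio of that library to the mean of old replicates 1 and 2 was -0.85 over B cell and -0.74 over MHC class II members, against -0.07 over mast cell members and -0.28 (SD 0.14) over 9 macrophage core genes, a list chosen after seeing the data.

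**Figure D3:**
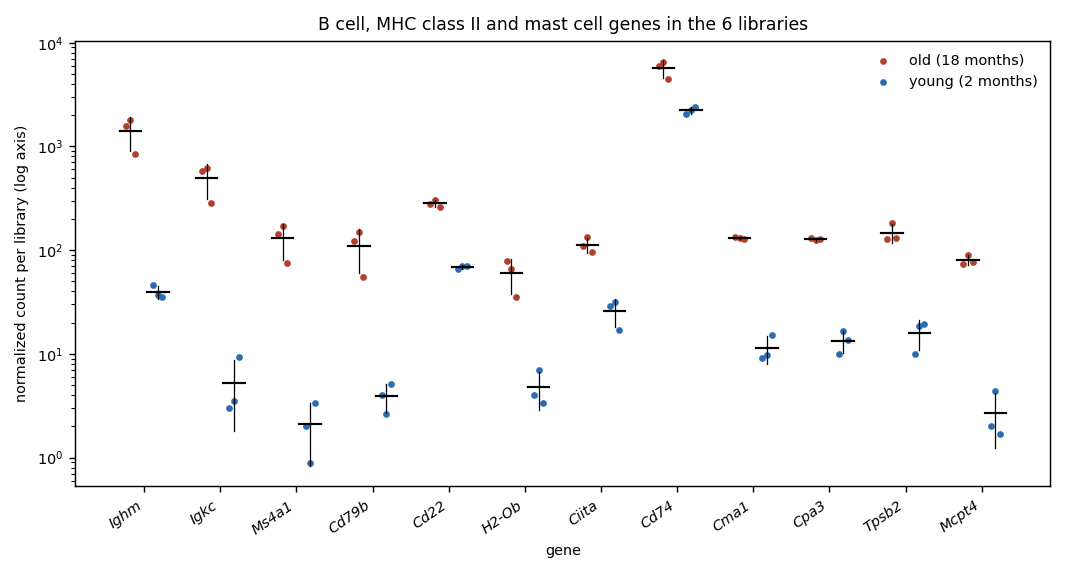
Normalized counts (vertical axis, log scale) of B cell genes (Ighm to Cd22), MHC class II genes (H2-Ob, Ciita and Cd74) and mast cell genes (Cma1 to Mcpt4) in the 3 old (red) and 3 young (blue) libraries, with black bars for means and thin lines for 1 SD either side. Ighm was at 1408 in old and 39.5 in young libraries, and the lowest old value of each B cell gene belongs to replicate 3.

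Energy metabolism differed by small amounts. Glycolysis genes had 7 members higher and 4 lower of 18, 11 adjusted over the list alone (median 0.14, camera adjusted p = 0.531), with the hexokinase gene Hk3 at 0.66 and Hk2 at -0.72. Without old replicate 1 or young replicate 2 the glycolysis counts were 3 higher and 3 lower, and without old replicate 2 or young replicate 1 they were 3 and 4. With 1 library left out, the glycolysis median ran from 0.08 (without young replicate 1) to 0.22 (without young replicate 3). Nuclear genes of oxidative phosphorylation had a median of 0.18 (camera adjusted p = 0.0174; adjusted p = 0.713 with an estimated correlation), and 4 of 25 members were higher and 1 lower, 5 adjusted over the list alone, with Ndufa1 at 0.59 and Uqcrq at -0.68. This list lost its call without old replicate 2 (camera adjusted p = 0.0939), without young replicate 1 (0.0626), and with length and GC trends removed (0.208, median 0.10), its adjusted p ranged from 1.42e-05 to 0.285 over 20 alternatives, and its median was 0.31 without old replicate 3, where 18 members were higher and 1 lower, while without young replicate 3 these counts were 8 and 1.

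The lists of mitochondrially encoded, ribosomal protein and unfolded protein and heat shock genes had been fixed, like the immediate early list, as signs of RNA and cell quality. Mitochondrially encoded genes had 5 of 7 members lower and 0 higher, 6 adjusted over the list alone, with a median of -0.65 (camera adjusted p = 0.00175; adjusted p = 0.339 with an estimated correlation), led by mt-Nd5 at -0.84 and mt-Cytb at -0.72. Ribosomal protein genes had 1 member higher (Rpl39l, 1.47) and 1 lower (Rpl13a, -0.47) of 77, 2 adjusted over the list alone (median 0.04, camera adjusted p = 0.613). Without old replicate 3 the ribosomal list passed with a median of 0.16, 28 members higher and 2 lower (camera adjusted p = 0.000914, range 1.03e-06 to 0.799). With an estimated correlation it did not pass there (camera adjusted p = 0.673). Without old replicate 2 it had 1 higher and 3 lower. The unfolded protein and heat shock list had 4 higher and 3 lower of 16, 7 adjusted over the list alone, with a median of -0.10, a mean of 0.10 and test directions that differed between camera and fry (camera adjusted p = 0.806). The heat shock gene Hspa1b was 3.69-fold higher in old and Trib3, a pseudokinase gene of the amino acid response, 2.56-fold higher in young.

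The share of reads on TEC gene models, short loci that await experimental evidence and mostly lie inside other genes, was 0.0671%, 0.0633% and 0.207% in old replicates 1 to 3 and 0.236%, 0.212% and 0.0959% in young replicates 1 to 3. With this measure as a covariate, added after seeing the data, 5379 genes and 16 lists passed, oxidative phosphorylation (camera adjusted p = 0.285) and complement (0.0846) lost their calls, cholesterol synthesis gained one (0.0436), and ribosomal protein genes went to 1 member higher, 33 lower and a median of -0.10 (camera adjusted p = 0.000966). With an estimated correlation neither cholesterol synthesis (camera adjusted p = 0.313) nor ribosomal protein genes (0.459) passed.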

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

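Of the tests below, those of depth, of other cells, of MHC class II, of dilution, of length and GC content and of other splits were chosen only after the result was seen.

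Members of the cell type lists that lay below the filter were summed, since the main comparison left them out. Of these sums, 4 of 7 were higher in every old library than in every young one. The fit without the filter used the same reads. T and NK cell members (16 genes) summed to 119 ± 25.7 normalized counts in old and 8.26 ± 2.77 in young libraries (SD, n = 3 each), from 341 and 27 reads. The sums for eosinophil and mast cell members (5 genes) were 38.8 and 16.9, and those for dendritic cell members (8 genes) were 31.7 and 14.3. B cell members (2 genes) summed to 6.97 in old, from 21 reads, against 0 reads in young.

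B cell, mast cell and MHC class II transcripts were higher in the old libraries, and 3 of 16 B cell and 4 of 7 mast cell members also had a mean of at least 10 in young. With every library thinned to 8163000 reads 13 of 14 tested B cell members were still called higher in old (limma). Thinning of this size could hardly remove a list median of 4.35, so that result does not decide on depth. Read totals overlapped between the ages. B cell members fell together in old replicate 3, with a median log2 ratio to old replicates 1 and 2 of -0.85 (SD 0.41, n = 16). Mast cell members (-0.07, SD 0.18, n = 7) and macrophage core genes (-0.28, SD 0.14, n = 9) fell less or not. Other cells in the old cultures, with B cells in an amount that differed between libraries, would give this pattern. It rests on old replicate 3, which also had the highest share of reads on ribosomal RNA genes other than the mitochondrial ones (1.35%). Its share on TEC gene models (0.207%) was the highest of the old libraries. Whether the quality of that library gave the pattern was not tested. The rise of MHC class II members in replicate 3 was 0.455 of that in the other old libraries, inside the B cell range of 0.0361 to 1.04 (median 0.507), but the mast cell median of 0.951 lies inside that range too, so the test does not decide whether MHC class II transcripts came from B cells. Expression of the MHC class II genes by the macrophages themselves stays equally open, as does age itself, which was not tested. The washing off of unattached cells would have removed some but not necessarily all B cells and mast cells.

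Cell cycle genes were lower in the old libraries. Dilution by RNA of other cells is argued against as the whole cause, since the median of the macrophage core genes was 0.38 where that of the cell cycle genes was -2.37 (SD 1.21, n = 25). Length and GC content are argued against too, since with their trends removed the cell cycle median was -2.43. A different mix of macrophages, timing of the inflammation and age stay open and were not tested.

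Reads on TEC gene models differed between libraries of 1 age. Models inside a gene on the same strand (852) differed 3.87-fold between the highest and lowest of the 6 libraries, and 3.50-fold within old and 2.51-fold within young. Models that overlap no gene (162) differed 1.75-fold over the 6 libraries and within old, and 1.44-fold within young. Genomic DNA was predicted to give similar ratios for both kinds of model, and they were not similar. Its reads would add to different starting levels, however, so these ratios cannot exclude a share of DNA. Models that overlap no gene were also higher in old replicate 3 (1803.5 normalized counts) than in old replicates 1 and 2 (1069.5 and 1031.7). The gap between the ratios is what was predicted for unspliced RNA in an amount that differed between libraries. No biological explanation was tested.

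Of the 10 splits of the 6 libraries into groups of 3, the real one gave 4183 genes (limma) and the highest of the others 0, so 1 of 10 reached the real value. For lists the real split gave 16 (camera) and the others 6 to 13, again 1 of 10. Those other splits called 0 genes. Their groups hold unequal numbers of old and young libraries, so part of the age difference stays between the groups. The rest of it widens the spread within them. Neither count is therefore what a comparison without an age difference would give. Splits of 3 against 3 are too few for a share under 0.05. The split of old replicates 1 and 2 with young replicate 3 against the rest, which follows the TEC share, had 2196 genes at an unadjusted p under 0.05, where the other 8 had 18 to 68.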

How the results depend on the processing

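The alternatives with length and GC trends removed, with the TEC covariate, with protein-coding genes only and without both libraries numbered 3 were chosen after seeing the data, most of them with their counts already seen.

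Of the 4183 genes, 0 were called in the opposite direction under any of 22 alternatives. Counts moved by more than 1.5 times under 4. Array quality weights gave 7634 genes (3875 higher, 3759 lower), and leaving out both libraries numbered 3 gave 6964 (3568 and 3396). The replicate number as a block gave 2643 (1281 and 1362), though libraries of 1 number did not resemble each other once the age means were removed (correlations across genes of -0.38, -0.36 and -0.68), so the numbers are not taken as pairs. An absolute log2 fold change of at least 1 left 1040. Apart from that limit, the cause was not tested. Leaving out each library gave 2927 to 5685 genes, 1442 to 2785 higher and 1485 to 2900 lower, and 15 to 18 lists. edgeR called 4324 and DESeq2 3743. Quantile normalization (4526) and median centring (4514) raised the share of higher genes from 50.4% to 54.4% and 60.3%, and the largest shift of the median of all genes was 0.054 on the log2 scale, under median centring.

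With an estimated correlation 0 lists passed in camera, where fry called 17 and 3 had an unadjusted camera p under 0.05. Estimated correlations ran from -0.06 (neutrophil) to 0.85 (oxidative phosphorylation), where the preset was 0.01. The eosinophil and mast cell list lost its call at an estimated correlation of 0.022, near the preset (camera p of 1.15e-06 and 0.00924). This argues against the correlation alone as the reason for the loss in that list. How far the difference in correlation explains the other lost calls was not tested. The test fry asks another question, namely whether a list's genes move one way. Of 538 list values 515 kept their direction and side of the threshold, 9 lost a call, 13 gained one and 1 reversed. The reversal was the ribosomal protein list with the TEC covariate, at a median of -0.10 (camera adjusted p = 0.000966, range over alternatives 1.03e-06 to 0.799), and its cause was not tested. With an estimated correlation the camera adjusted p of this reversal was 0.459. The calls lost were of oxidative phosphorylation, complement and the lysosome list.

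Of 2709 values of 124 named genes 2689 kept direction and side of the threshold, 16 lost a call, 4 gained one and 0 reversed. The calls lost included those of Fdps, Sdhc and Batf3. The adjusted p of Fdps was 0.0624 without young replicate 1 and 0.0720 without young replicate 2. Batf3 lost its call without old replicate 1 (0.151), old replicate 2 (0.114), young replicate 1 (0.0687), young replicate 2 (0.127) and young replicate 3 (0.0586). Gpr18, fitted without the filter throughout, passed with protein-coding genes only (limma adjusted p = 0.0341, range 0.0341 to 0.261), and with 23 reads in old and 9 in young its comparison is limited by depth.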

Other observations

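The segment shares were looked at only after the B cell genes had been seen, and the 3 list tests were chosen before their results were seen but after single genes were.

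A single heavy chain and a single kappa chain segment made up most immunoglobulin V reads of the old libraries. Ighv11-2 held 78.7%, 76.9% and 81.7% of heavy V reads in old replicates 1 to 3 and Igkv14-126 held 84.4%, 86.2% and 82.7% of kappa V reads. The next segments held 1.63% and 1.86% of the pooled old reads. The young libraries held 7 of 22 and 2 of 16 such reads.

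A lower amino acid starvation and serine synthesis response was tested because Phgdh was low. In a list without Phgdh 0 of 23 members were higher and 21 lower in old, with a median of -0.72 (camera p = 1.84e-12; p = 0.0566 with an estimated correlation). This is consistent with a lower response in the old cultures, as a hypothesis found and tested on the same libraries.

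A lower TGF-beta and SMAD response was tested because Pmepa1 was low. In the list 4 of 15 members were higher and 8 lower in old. Its camera p was 0.0437. A higher PPAR-gamma and fatty acid oxidation response was tested because lipid genes were high. In that list 4 of 18 members were higher and 1 lower in old, and the camera test over all tested genes gave 0.0475. Neither value was under 0.05 divided by the 3 lists, so both remain undecided.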
